A study of Mus musculus with 2 samples.

How the data were processed

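Total RNA from whole embryo proper of mice was measured on 1-colour oligonucleotide arrays, per the labels with a biotin-UTP label and the CodeLink Expression Bioarray protocol (a system with 1 oligonucleotide probe per spot). There were 2 samples, 1 array per group. Per the series' design text, each RNA came from a pool of litter-matched embryos collected at E8.5 (embryonic day 8.5), 42 wild-type embryos and 45 homozygous mDom mutant embryos. mDom (mDomino, p400) is the name the submitters use for the gene whose present symbol is Ep400, which encodes the ATPase subunit of the TIP60/p400 chromatin-remodelling complex. Groups were taken from the sample titles.

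The deposited values were spot intensities on a linear scale, 1 column per array, which per the labels came from images analysed with the CodeLink System Software. The software version, the background correction, the scaling and any detection flag are not given in the sources used here. That the values were linear and already scaled per array was read from the table: they included negative numbers, reached 1374 in the wild-type column and 1714 in the mDom-/- column, and had medians of 1.05 in both. Whether the authors centred on the median of a subset of probes stays unknown. The code -9999 was read as no value, for 105 wild-type and 106 mDom-/- probes. Control spots were not told apart from other probes, so all probes with a value entered the scaling.

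The table held 36227 probes. In the platform annotation, 21615 probes had 1 gene symbol, 681 had several and 13931 had none listed. No gene was named from a probe with several symbols. Of the probes with 1 symbol, 21487 had an Entrez identifier found in the RefSeq gene table of GRCm38.p6, which was used for current symbols, synonyms and gene order only. The build behind the probe design is not given in the sources used here, so no coordinates are reported.

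Each array was divided by its own median, raised to a common floor and put on the log2 scale, and the log2 ratio was taken as mDom-/- minus wild-type. The floor was the higher of the 40th percentiles of the 2 arrays, 0.541 times the array median, and 59.7% of wild-type and 60.0% of mDom-/- probes lay above it. A probe was compared when at least 1 array was above the floor (23042 probes) and counted as measured on both when both were (20167 probes). Where only 1 array was above the floor, the ratio is a bound, written as "at least N-fold". A gene took the value of its probe with the highest mean log2 intensity. This gave 13136 compared genes, 11926 of them measured on both arrays and 1704 with several compared probes.

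With 1 array per group there is no spread between replicates, no test and no p-value, and the number of arrays limits the precision. The pools average over embryos but give no measure of how embryos or litters differed. Genes were therefore described by a rule of size, at least 2-fold apart. The only repeated measurement within the arrays was pairs of probes of 1 gene: over 1442 genes with 2 probes measured on both arrays, the SD of a log2 ratio derived from the difference within pairs was 0.25 (95% bootstrap interval 0.23 to 0.26). It covers probe and hybridisation error, not the spread between pools. Ratios were wider among dim genes: the robust SD of the log2 ratio was 0.35 in the dimmest 25% of the genes measured on both arrays and 0.19 in the brightest 25%.

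Before the data were examined, 27 gene lists, the size rule, the floor, the rule for named genes and the alternatives were fixed. For the 25 lists with at least 3 compared members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins and drawn with replacement within a bin. A list was called apart from the random lists when its percentile was under 2.5 or over 97.5. By chance 1.25 of 25 lists would be called so if list members varied independently. Members of a list can move together, so this is not the expected number of false calls. The percentile describes these 2 arrays and is not a p-value. The globin and Hox lists were fixed with knowledge of published work on this mutant, so they are not independent evidence of a direction. Early embryo, later embryo, red-cell-restricted and second p53 target lists and the gene families of the closing section were added after the data had been seen.

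Named genes were Ep400, every compared globin gene, each Hox gene at least 2-fold apart, the 10 highest and 10 lowest ratios among genes measured on both arrays, the 3 largest bounds in each direction, up to 4 members of each list called apart, and the sex-linked list. Gene models with only a clone or accession name were left out. Genes named outside this rule are marked as such.

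Alternatives were no rescaling, scaling to the 75th percentile, quantile normalization, loess on mean brightness (span 0.3), floors at the 25th or 60th percentile or none, the mean over a gene's probes, size rules of 1.5-fold, 3-fold and 3 robust SDs, and lists restricted to members measured on both arrays. On data simulated from the wild-type array with the probe-pair SD as noise, 98 of 100 genes changed 3-fold, 6 of 100 changed 1.5-fold and 0 of 12447 unchanged genes passed the 2-fold rule, in a step run on 12707 genes. The changed genes were all well above the floor, and the noise was the same for bright and dim genes. These shares are therefore no error rate for dim genes or bounds. In the same simulation 5 of 100 lists drawn at random from bright genes were called apart. Their noise was independent between genes, so this does not cover lists whose members move together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.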

Results

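Gene expression was compared between pools of wild-type and mDom-/- mouse embryos at E8.5, when the neural tube is closing, the heart tube has begun to beat and primitive red cells made in the yolk sac are entering the embryo. The question set by the design was which transcripts of the embryo proper differ in embryos homozygous for a mutation of mDom. Whether these embryos lacked the p400/mDomino chromatin-remodelling ATPase was not measured here. One array was hybridised per pool, with 42 wild-type and 45 mDom-/- embryos. Intensities are given in units of the array median. No value below has a replicate error. The only internal yardstick is the SD of 0.25 on the log2 scale between probes of the same gene.

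Ep400, the disrupted gene, could not be used to check the labels. Its 2 probes read 0.215 and 0.470 on the wild-type array and -0.029 and 0.071 on the mDom-/- array, all below the floor of 0.541. Whether either probe lies inside the disrupted part of the gene is not given in the sources used here.

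The profiles of both pools were close: over the 11926 genes measured on both arrays, Pearson's r of the log2 intensities was 0.988 and Spearman's rho 0.987, across genes, which are not independent replicates. Of 13136 compared genes, 111 were at least 2-fold higher and 122 at least 2-fold lower in the mDom-/- pool. Among them, 65 of the higher and 71 of the lower genes were measured on both arrays, and the others were above the floor on 1 array only. The lowest ratios measured on both arrays were those of Hbb-y and Hba-x, the embryonic beta-like and alpha-like globins, followed by Casp12 (6.81-fold lower), Olfr921 (3.85-fold), Nppb, a natriuretic peptide of heart muscle (3.56-fold), Zic1, a transcription factor of the dorsal neural tube (3.33-fold), Tmem43 (3.15-fold), Pebp1 (3.13-fold), Uba6 (3.12-fold) and En2, a midbrain-hindbrain homeobox gene (2.90-fold). A second, dimmer probe of Uba6 had a log2 ratio of 0.02, so its probes disagreed.

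The highest ratio measured on both arrays was that of the chemokine receptor gene Ccr9, from 0.561 in wild-type to 15.5 in the mDom-/- pool. Csnk1g2, a casein kinase gene, was 5.52-fold higher, Pifo 4.19-fold, Ltbp4, which encodes a TGF-beta binding protein, 3.94-fold, Ttc28 3.58-fold, Prph, a neuronal intermediate filament gene, 3.34-fold, and Gramd2, Aqr, Ptgds and Celf5 between 3.28-fold and 3.33-fold. Among genes above the floor on 1 array only, the largest bounds were for Mmp16 (at least 20.6-fold higher), Loxhd1 (at least 16.0-fold higher) and Nlrp2 (at least 13.3-fold higher), and for Cdh23 (at least 20.8-fold lower), Cyp21a1 (at least 6.27-fold lower) and Pcdhb12 (at least 6.05-fold lower). Each of these 6 genes had 1 compared probe. Where a gene at least 2-fold apart had a second compared probe (13 of 233 genes), that probe had the same sign in 8 and was itself at least 2-fold apart in the same direction in 1. The number of genes past the rule moved with the floor, from 38 higher and 28 lower at the 60th percentile to 533 higher and 522 lower at the 25th. With the 60th percentile floor, which compresses ratios of dim genes, Pifo, Ttc28, Gramd2, Aqr, Celf5, Olfr921, Nppb, Tmem43, Cyp21a1 and Pcdhb12 were under 2-fold, with log2 ratios from 0.30 (Celf5) to 0.92 (Pifo) and from -0.39 (Nppb) to -0.94 (Cyp21a1). At that floor Ccr9, Mmp16, Loxhd1, Nlrp2 and Cdh23 shrank to log2 ratios of 3.14, 2.66, 2.30, 2.03 and -2.67.

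**Figure D1:**
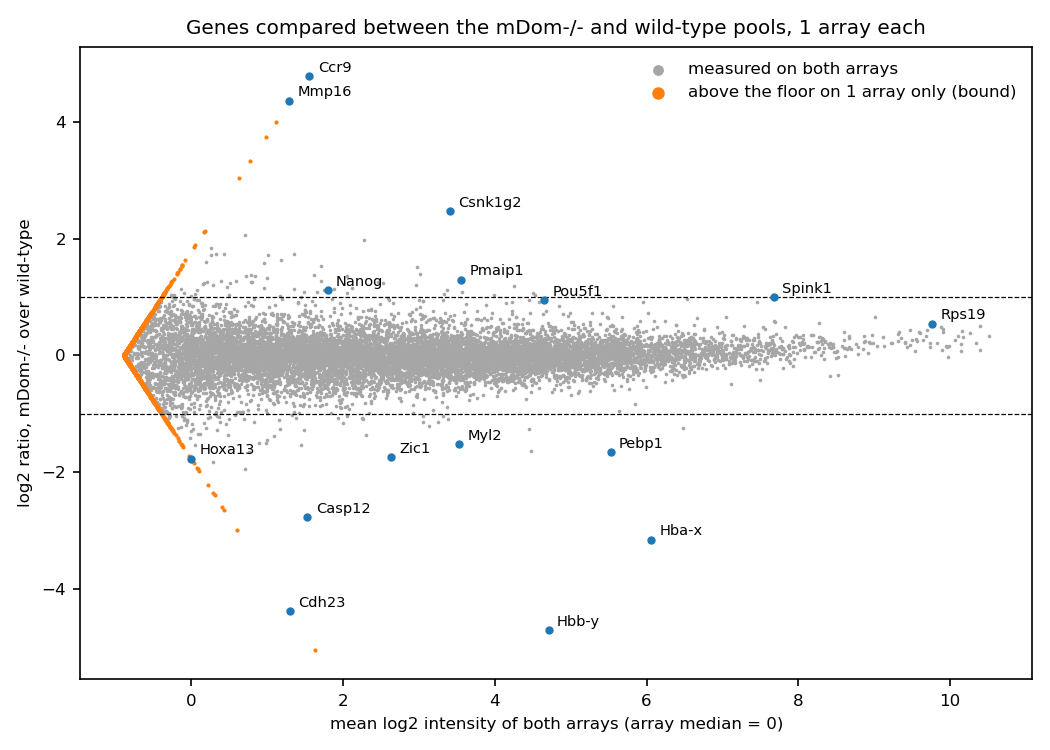
Log2 ratio of mDom-/- over wild-type against mean log2 intensity for the 13136 compared genes, 1 point per gene; orange points are bounds, blue points are labelled genes, and dashed lines mark 2-fold. Hbb-y and Hba-x stand apart from genes of like brightness, and ratios widen toward the dim end.

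Embryonic globin signal was far lower in the mDom-/- pool. Hbb-y read 133.8 in wild-type and 5.12 in the mDom-/- pool, 26.2-fold lower, and Hba-x read 199.9 and 22.4, 8.91-fold lower. These were the only globin genes with a probe of their own. Of 4 probes annotated to several genes including a globin, 3 were between 4.57-fold and 4.86-fold lower, and 1, which also matched the widely expressed Ost4, had a log2 ratio of -0.04. The probes with several genes were outside the rule for named genes and were taken up after their values were seen. Over all scaling and floor alternatives the log2 ratio of Hbb-y stayed between -4.72 and -4.69 and that of Hba-x between -3.23 and -3.13.

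Of the 18 compared genes of the erythroid list, 9 were bright enough to show a difference as large as that of the shared globin probes, and none did: their lowest log2 ratio was -0.82 (Cited4), while Ermap and Blvrb had 0.03 and -0.01. These 3 were named after their values were seen. Of 8 compared red-cell-restricted genes, a list added after the data had been seen, only Rhag and Alas2 were bright enough, with log2 ratios of -0.01 and -1.15, while Epb42, dimmer but measured on both arrays, had 0.45 and the other 5 were bounds. Of the 9 bright genes of the erythroid list, only Rhag was on this list. How far the others, Ermap among them, follow the share of red cells was not tested, so their values do not show whether it was kept. The erythroid list, which holds transcription factors and membrane proteins of red cells, had a median log2 ratio of -0.18 over 18 compared members, none of them 2-fold apart, and lay at percentile 2.83 of the random lists, within their range. That placement depended on the setting: the list lay below the random lists with quantile normalization (percentile 2.40), the 25th percentile floor (-0.43, percentile 0.05), the 60th (-0.24, percentile 1.54) and no floor (-0.41, percentile 0.14). Over the 11 members measured on both arrays the median was -0.02 (percentile 49.5). That restriction drops Gata1, Epor, Slc4a1, Hemgn, Rhd and Kel, below the floor in the mDom-/- pool only, and Gfi1b, below it in wild-type only. It therefore pulls the median toward 0 and does not count against a lower list. The heme biosynthesis list had a median of -0.16 (percentile 4.88), with 1 of 10 members at least 2-fold lower, Alas2, the erythroid form of the first enzyme of the pathway (2.22-fold), which was named after its value was seen. Only 2 megakaryocyte and platelet genes were compared, with a median of -0.07, and the macrophage and leukocyte list lay at percentile 49.0 with a median of -0.03 over 5 members.

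Hox genes, which set position along the body axis, were lower as a list for paralogues 9 to 13. Their list had a median log2 ratio of -0.38 and lay at percentile 0.06 of the random lists, with 9 of 10 compared members below 0. Hoxa13 was at least 3.41-fold lower and Hoxa10 2.20-fold lower, while Hoxa9 and Hoxc9 were 1.67-fold and 1.59-fold lower, short of the 2-fold rule. Hoxb13, Hoxc13 and Hoxd10, named after their values were seen, had log2 ratios of -0.05, 0.07 and -0.08. With the 60th percentile floor no Hox gene named here was 2-fold apart (Hoxa13 -0.06, Hoxa10 -0.58), while the list stayed below the random lists (-0.26, percentile 0.37). Paralogues 5 to 8 had a median of -0.20 (percentile 3.79) and paralogues 1 to 4 a median of -0.10 (percentile 18.8), both within the random lists, and no member of either was 2-fold apart. The difference between the 3 Hox lists was not tested. Quantile normalization and loess placed paralogues 5 to 8 outside the random lists as well, at percentiles 2.40 and 2.43.

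**Figure D2:**
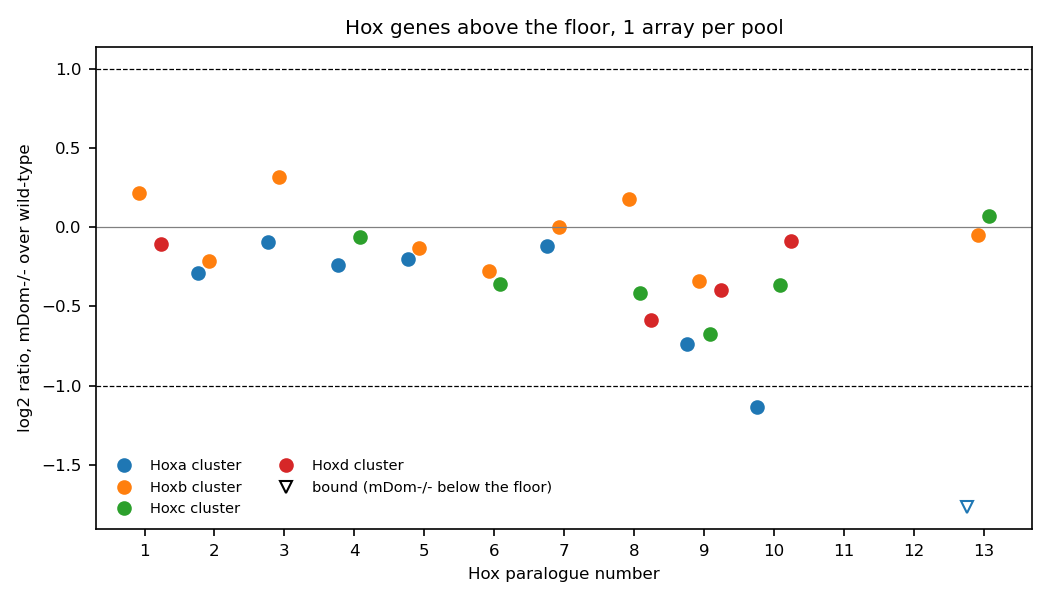
Log2 ratio of mDom-/- over wild-type for each Hox gene above the floor, by paralogue number (x axis) and cluster (colour); filled circles were measured on both arrays, the open triangle is a bound, and dashed lines mark 2-fold. Hoxa10 and Hoxa13 lie beyond the 2-fold line, both lower in the mDom-/- pool.

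Genes of heart muscle were lower as a list, with a median log2 ratio of -0.31 over 19 compared members, below every one of the 10000 random lists. The 4 members at least 2-fold lower encode sarcomere proteins: Myl2 (2.87-fold), Myh7 (2.72-fold; log2 ratio -0.90 with the 60th percentile floor), Tnni3 (2.22-fold) and Ttn (2.06-fold, with a log2 ratio of -0.57 over the mean of its 4 probes). Not all heart genes were lower. The atrial light chain gene Myl7 had a log2 ratio of 0.08, and the cardiac transcription factor genes Nkx2-5, Gata4, Isl1, Tbx20 and Hand1 lay between 0.04 and 0.16, while those of Tbx5 and Mef2c were -0.14 and -0.18. These were named after their values were seen.

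Endothelial genes were lower as a list too, with a median of -0.33 over 16 compared members (percentile 0.03) and 13 members below 0. Emcn, which encodes endomucin, was 2.13-fold lower and Pecam1, a junction protein gene, at least 2.11-fold lower. Pecam1 and Cldn5 were not compared with the 60th percentile floor. Cldn5 was at least 1.97-fold lower and Plvap 1.80-fold lower, short of the rule. A second, dim probe of Plvap had a log2 ratio of -0.28, a bound, and the mean over its probes was -0.57.

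Genes of pluripotent cells and the germ line were higher as a list, with a median log2 ratio of 0.32 over 16 compared members, above every random list. In it 13 members lay above 0 and 3 below. Those below, Kit (-0.47), Ddx4 (-0.34) and Mael (-0.09), were named after their values were seen. The germ-line genes Ddx4, Mael, Stra8 and Hormad1 were bounds and went both ways. The pluripotency transcription factor gene Nanog was 2.17-fold higher, Utf1 2.05-fold and Dppa5a 2.02-fold, and Pou5f1, brighter than these at 18.1 in wild-type and 34.9 in the mDom-/- pool, was 1.93-fold higher. With the 60th percentile floor Utf1 had a log2 ratio of 0.20 and Dppa5a was not compared, and the list median was 0.20 (percentile 99.3). Gut endoderm genes were also higher as a list (median 0.28, percentile 99.9, 12 members), with the gut peptide gene Pyy 2.09-fold higher and the trypsin inhibitor gene Spink1 at 144.5 in wild-type and 289.3 in the mDom-/- pool, with a second probe at 1.08 on the log2 scale, but a log2 ratio of 0.89 with quantile normalization and 0.84 with loess. Sox17 and Trh had log2 ratios of 0.52 and 0.43, and 3 members lay below 0.

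Lists for other tissues of the embryo lay within the random lists at the chosen setting. The neural tube and brain list had a median of -0.12 (percentile 8.55), but 4 of its 21 compared members were at least 2-fold lower and none 2-fold higher. These were Zic1, En2 and, named after their values were seen, the Notch target Hes5 (2.83-fold) and the proneural gene Neurog2 (at least 2.75-fold). With the 60th percentile floor Hes5 had -0.82 and Neurog2 was not compared. The neural crest list had a median of -0.05 (percentile 28.2), but lay below the random lists with quantile normalization (-0.173, percentile 2.03) and loess (-0.178, percentile 1.89), with Sox10 and Tfap2a 2.30-fold and 2.28-fold lower, also named after their values were seen (Tfap2a not compared with the 60th percentile floor). The somite and presomitic mesoderm list had a median of 0.11 (percentile 96.2) with no member 2-fold apart. Among tissues that dissection could carry along, visceral endoderm and yolk sac genes went both ways, with 9 of 19 members above 0, a median of -0.01 (percentile 30.3) and 0.12 (percentile 95) with the 60th percentile floor. Apoc2, Apoa4, Ctsh and Ttr were 1.89-fold, 1.73-fold, 1.58-fold and 1.51-fold higher. Lrp2 and Cubn were 1.67-fold and 1.53-fold lower, and all of these genes were named after their values were seen. The median was -0.06 for trophoblast and decidua genes (percentile 37.6, 6 members). It was 0.13 (percentile 88.3) with the 60th percentile floor and 0.12 (percentile 87.0) over members measured on both arrays. Among sex-linked genes, Xist, expressed from the inactive X, had a log2 ratio of -0.41, and the Y-linked Eif2s3y and Kdm5d had 0.25 and 0.06. Their list lay at percentile 71.7.

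**Figure D3:**
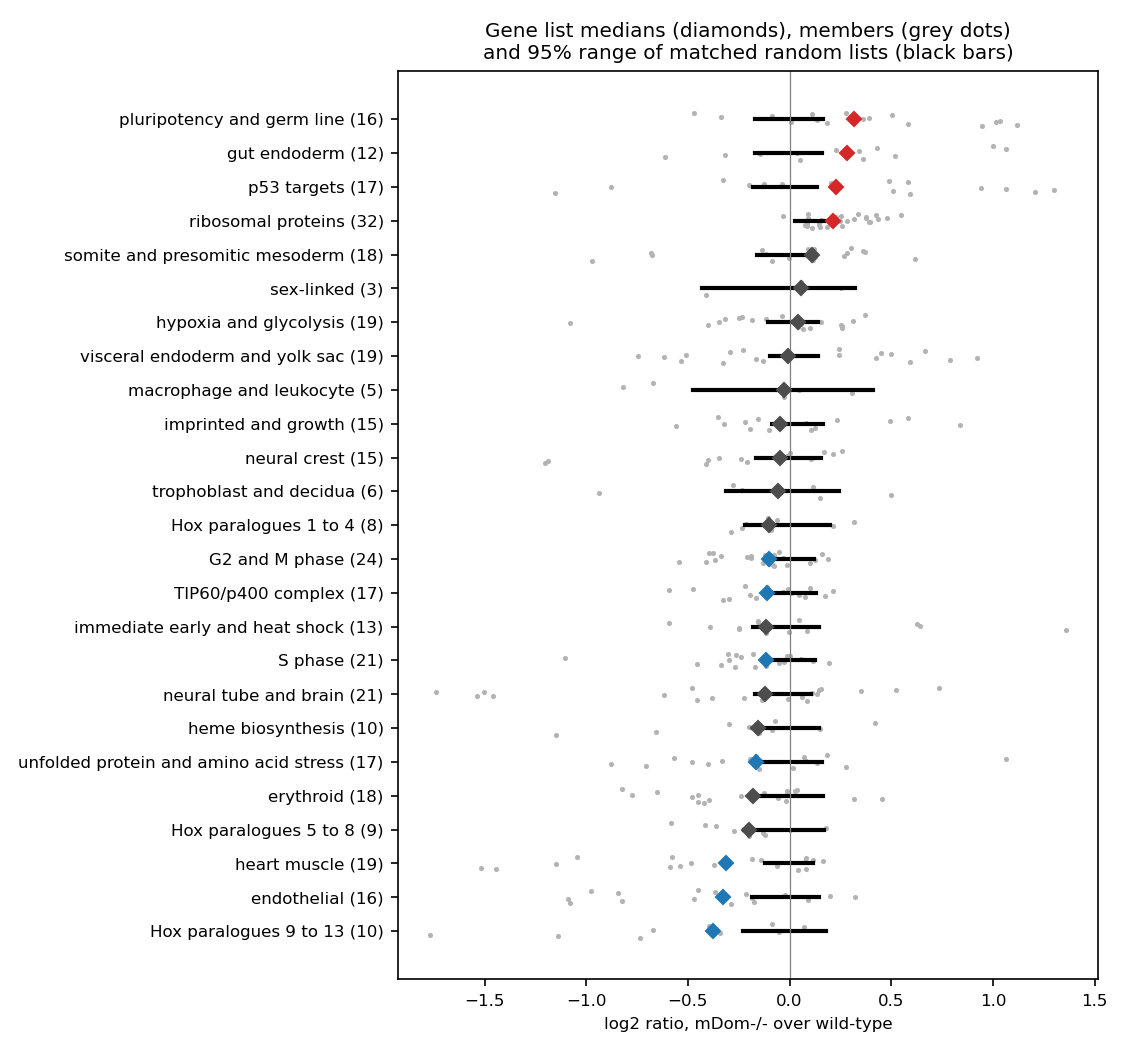
Median log2 ratio of mDom-/- over wild-type (x axis) for each of the 25 gene lists with at least 3 compared members (number in brackets), as diamonds, blue where lower and red where higher than the random lists; grey dots are member genes and black bars span the central 95% of 10000 matched random lists. In all, 7 lists lie below and 4 above the bars.

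Targets of p53, the transcription factor activated by DNA damage and other stress, were higher as a list, with a median log2 ratio of 0.23 over 17 compared members (percentile 99.9). Pmaip1 (Noxa, a cell death gene) was 2.46-fold higher, Ccng1 2.31-fold and Sesn2 at least 2.09-fold (not compared with the 60th percentile floor), and Phlda3 was 1.92-fold higher. Members did not all go the same way: Mdm2, which encodes the ubiquitin ligase of p53, was at least 2.23-fold lower (not compared with the 60th percentile floor), and 7 of the 17 lay below 0. With that floor the list median was 0.47 over 13 members (percentile 100).

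The S phase and the G2 and M phase lists were lower by small amounts, and by more with loess (medians of -0.21 and -0.17). The S phase list had a median of -0.12 (percentile 0.51), with 17 of 21 compared members below 0 and 1 at least 2-fold lower, the DNA polymerase gene Pola1 (2.15-fold; not compared with the 60th percentile floor). The replication helicase genes Mcm7 and Mcm6 had log2 ratios of -0.46 and -0.34 and Slbp -0.30, while Rrm2 and Cdt1, named after their values were seen, had 0.19 and 0.11. Replication-dependent histones, a family chosen after the data had been seen, had a median of 0.79, from wild-type signals of at most 3.14. The G2 and M phase list had a median of -0.10 (percentile 0.71), with 20 of 24 members below 0 and none 2-fold apart. Its lowest members, the mitotic kinase genes Plk1, Aurka and Ttk and the phosphatase gene Cdc25c, lay between -0.55 and -0.37, and a second probe of Aurka had -0.01. The list of unfolded protein and amino acid stress genes was lower (median -0.17, percentile 0.82, 17 members). Herpud1 and Trib3 were at least 1.84-fold and 1.63-fold lower (not compared with the 60th percentile floor), and Phgdh and Pdia4 had -0.57 and -0.48. Of the 17 members 7 lay above 0, among them Sesn2, also in the p53 list, and Atf4 (0.28), named after its value was seen.

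Genes of the TIP60/p400 complex had a median of -0.11 over 17 compared members, Ep400 not among them, and lay at percentile 1.99. None was 2-fold apart, and the lowest were Mrgbp (-0.59), Actl6a (-0.47), the acetyltransferase gene Kat5 (-0.33) and Trrap (-0.30). The placement of this list outside the random lists was lost in 5 alternatives, at percentiles from 2.57 to 9.25. Ribosomal protein genes had a median of 0.22 (percentile 99.9), with 31 of 32 members above 0, led by Rps19 (0.55), Rps4x (0.48), Rps3 (0.44) and Rps20 (0.42; its second, much dimmer probe -0.04), but the median was about 0 and within the random lists with quantile normalization (-0.00333, percentile 66.6) and loess (-0.0105, percentile 81.8). Their random lists of like brightness had a median of 0.10, so the brightest genes as a whole read higher on the mDom-/- array. The immediate early and heat shock list (median -0.11, percentile 10.97), hypoxia and glycolysis list (0.04, percentile 65.0) and imprinted and growth list (-0.05, percentile 10.02) lay within the random lists. The imprinted list lay below them with quantile normalization (percentile 2.46) and the mean over probes (percentile 2.18). The hypoxia median was below 0 with quantile normalization, loess (-0.075), the other floors and no floor, still within the random lists.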

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

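Both tests of the globin signal in this part were chosen after the result was seen and redefined once. Globin signal was lower on 3 probes that were left out of the named genes because their annotation lists several genes, with log2 ratios of -2.27, -2.28 and -2.19.

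Against a single faulty probe or spot, 5 of the 6 globin-annotated probes were lower by more than 3 probe-pair SDs. Fewer red cells, or less blood, in the mDom-/- pool may account for the pattern and stays open: of the red-cell-restricted genes only Alas2 (-1.15) and Rhag (-0.01) were bright enough to show a difference as large as the smallest of these 5, and their median of -0.58 rests on too few genes to decide. That count depends on which genes the list holds, a choice made after the data had been seen. Ermap (0.03), a bright gene of the erythroid list, was not on it. In their first form both tests took the probe shared with Ost4 (-0.04) as the smallest globin difference; the faulty probe then stayed undecided, and the median of all 8 compared red-cell-restricted genes, -0.27, met what fewer red cells would give, although 5 of these were bounds near the floor and Epb42 had 0.45. That median was -1.27 with the 25th percentile floor and -1.15 with none, values that rest on such dim genes and decide nothing. An effect of the mutation on globin transcription within red cells was not tested and stays open too.

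Probes with no gene name in the annotation also differed between the pools: of 7586 compared, 58 were at least 2-fold higher and 61 at least 2-fold lower in the mDom-/- pool, a share of 1.57% against 1.77% of named genes. The widest log2 ratios among those measured on both arrays were -4.40 and 2.93.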

How the results depend on the processing

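No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. Scaling hardly moved the counts of genes at least 2-fold apart: over no rescaling, 75th percentile, quantile and loess, 110 to 114 were higher and 117 to 122 lower. The floor moved them most, to 533 higher and 522 lower at the 25th percentile, 38 and 28 at the 60th, and 1200 and 1129 with no floor. All 38 higher and 28 lower genes at the 60th percentile were among those of the chosen floor. A higher floor can only shrink a probe's ratio, so this overlap says little about stability. The 1.5-fold rule gave 536 and 571, the 3-fold rule 22 and 23, and 3 robust SDs 162 and 140, with more higher than lower. The probe-pair SD was 0.36, 0.19 and 0.94 at the 25th percentile floor, the 60th and none, so depth of signal over background limits the dim genes. One Ep400 probe counted with the 25th percentile floor (log2 ratio -0.97, a bound) and 1 with no floor (-2.72). Of 243 list values, 206 kept their placement and moved by less than 1 SD of the random lists. The cause of the other shifts was not tested. The ribosomal protein median lay just below 0 with quantile normalization (-0.00333, percentile 66.6) and loess (-0.0105, percentile 81.8), within the random lists. The TIP60/p400 list lost its placement with the 75th percentile (-0.0904), quantile (-0.101), loess (-0.098), the 60th percentile floor (-0.0724) and the mean over probes (-0.113). Lists that gained one were erythroid (quantile -0.181, floors -0.43, -0.24 and, with none, -0.41), Hox 5 to 8 (quantile -0.206, loess -0.212), neural crest (quantile -0.173, loess -0.178), and imprinted and growth (quantile -0.131, mean over probes -0.099). Lists that only moved were, with loess, S phase (-0.21), G2 and M phase (-0.17), hypoxia (-0.075) and imprinted (-0.131), and with quantile normalization hypoxia (-0.0314). With the 25th percentile floor they were megakaryocyte (-0.34) and hypoxia (-0.035). The 60th percentile floor moved Hox 1 to 4 (0.0623), Hox 9 to 13 (-0.26), visceral endoderm (0.12), trophoblast (0.13), p53 targets (0.47), hypoxia (-0.0349) and pluripotency (0.20). Having no floor moved hypoxia (-0.0349), pluripotency (0.48) and sex-linked genes (-0.18). Restriction to members measured on both arrays, which drops those below the floor on 1 array, moved erythroid (-0.0179), trophoblast (0.116) and p53 targets (0.36). No named gene reversed in these alternatives, and 50 of 572 gene values moved by more than the probe-pair SD.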

Other observations

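The histone and collagen families, the neighbours of Ep400 and the tests of brightness scaling and handling stress were chosen after the result was seen, while the predictions for the early, later and second p53 lists were written before. Replication-dependent histone genes, which package new DNA, were higher in the mDom-/- pool: the median log2 ratio of 12 compared genes was 0.79, above every one of 10000 random lists, with 10 above 0. H2bc18 was 2.43-fold higher, H3c8 2.21-fold and H2bc9 2.05-fold (not compared with the 60th percentile floor), while H3c7 and H4c18 lay at -0.19 and -0.07. These genes have near-identical copies, so values of single genes are uncertain. Their probes may also read the same transcripts, unlike those of genes in the random lists, so the rank can overstate the difference. A further 11 probes shared by several histone genes had a median of 0.39, with 7 above 0. The family median was between 0.43 and 0.81 over the alternatives.

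The family was found by looking through 22 gene-name patterns, of which 5 of the 21 with a percentile lay outside the random lists. The histone pattern was then narrowed, from 14 genes with a median of 0.71, and a broad pattern of 41 genes had 0.29. The others outside were collagens, Nduf genes of respiratory complex I (0.14, percentile 99.6) and laminins (-0.28, percentile 0.88). The 30 collagen genes had a median of -0.16 (percentile 1.12), with Col3a1 2.40-fold and Col11a1 2.11-fold lower, and lay within the random lists with the 60th percentile floor (-0.07) and the mean over probes (-0.12).

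Pluripotency genes were higher while heart muscle, endothelial and posterior Hox genes were lower, and 4 of 4 of these lists stayed outside the random lists with loess. The random lists were already matched on mean intensity, so loess adds little against a scaling error that depends on brightness. A candidate explanation for these lists was an earlier developmental stage of the mDom-/- pool, under which an early embryo list would be higher and a later embryo list lower. The early list had a median of 0.154 (percentile 97.1; 96.8 to 99.9 over the alternatives), with Pim2 2.23-fold higher (0.90 on the log2 scale as the mean of its probes), and the later list had 0.154 as well (percentile 96.2; 57.1 to 99.3). The later median met the bound written beforehand against a delay, at the chosen setting and in the alternatives. It is weak evidence, since the median was 0.02 with the 25th percentile floor and the members went both ways around a mean of -0.01. Most neuronal genes of the later list were higher, with Tubb3 2.01-fold and Ina, Nefm and Phox2a at 0.66, 0.55 and 0.51. Neurod1 (-0.81) and Elavl4 (-0.42) were lower. Col3a1 and Postn were 2.40-fold and 2.05-fold lower and Mybpc3 had -0.66, while Dcn had 0.35. This split by tissue was seen after the values and was not tested, so the question was not taken as decided. An earlier stage, of all tissues or some, other shares of tissues and an effect of the mutation on these genes stay open.

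A p53 response in the mDom-/- pool is a hypothesis for the higher p53 target list, and other p53 targets, none shared with that list, were to be higher if so. Their median was 0.178 over 14 compared genes (percentile 98.3), with 10 above 0 and none 2-fold apart, and between 0.175 and 0.201 over the alternatives. For general stress from handling, the immediate early and heat shock list had a median of -0.114 (percentile 10.97), and -0.06 with the 60th percentile floor. At the chosen setting this was more than 1 SD (0.082) below the random lists' median of -0.0125, which met the rule set against such stress. Handling stress was still left open, since the list had a mean of 0.07, with Ier3 2.57-fold, Hspa1a 1.56-fold and Hspa1b 1.54-fold higher. Mdm2, itself a p53 target, was at least 2.23-fold lower, against the direction of the list. Whether all cells or a few carried the pattern was not tested.

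Of 21 genes at least 4-fold apart, 15 were above the floor on 1 array only. A check of whether second probes repeat such ratios, planned before its result was seen, had 2 genes, with a median of -0.01 in the direction of the brighter probe. Among the compared genes nearest Ep400 in the gene order of GRCm38.p6, 2 of 50, 5 of 100, 6 of 200 and 8 of 400 were at least 2-fold apart, and as many or more were held by 303 of 1222, 29 of 1122, 166 of 922 and 198 of 529 windows of those sizes across the genome.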
